A study of Mus musculus with 462 samples.

How the data were processed

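Poly(A)+ RNA was measured after hybrid selection in 439 libraries of 462 samples of the series, each a clone of an F1 129/Castaneus mouse embryonic stem cell line. The other 23 samples (9 PRO-seq, 8 ATAC-seq and 6 ChIP-seq, that is 3 each for H3K27me3 and H3K4me3) were not analysed here. Per the labels, hybrid selection was done on a pool of barcoded libraries. The deposited values are whole-number counts per transcript, with 1 column per parental allele and no normalization by the authors that the values show. The genome build is mm9, per the submitters' processing notes. The aligner, the counting program, the assignment of reads to alleles and any filter are not given in the sources used here. That the columns are the parental alleles follows from the values and the series design, and which column is which strain is not stated. The growth protocol names male cells while the labels name a female line.

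The count files list 692, 903 or 908 transcripts, and fits were made only within libraries that share a list. Rows with the same counts as an overlapping row were dropped (1, 5 and 7 rows), 5 exon rows of linc1319 were kept apart, and 691, 898 and 896 rows were used. Of 1588 transcript names, 1542 matched the reference name tables. Coordinates are those of the files, 1-based. The total count of a transcript is the sum of both allele columns, so reads that cover no difference between the strains are not in it. Libraries held from 62149 to 3029484 such counts. Over all pairs of libraries that share a list, no pair held identical counts or differed by as little as sampling noise.

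Groups are those of the labels. The reference of a group was the Control clones of its own date label. The dates 151214 and 151214-S1 hold no Control clones, and their groups were set against all Control clones of the same transcript list. Gpr19-pAS, with clones of 2 dates, was set against the 9 Control clones of the 1 date that has them. The group linc1319-pAS-15kb has 1 clone and was not tested.

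Total counts were tested with edgeR 4.0.16 (TMM factors, quasi-likelihood F test, genes with a mean count of at least 10, Benjamini-Hochberg adjustment within a group, threshold 0.05), in R 4.3.3. Values are CPM of the allele-assigned total. Allelic imbalance was measured per clone as the log2 ratio of the columns with a pseudocount of 0.5, where a clone had at least 20 allele counts. The statistic was the mean absolute deviation from the pooled median, modified minus reference, because the labels do not name the modified allele. It was tested two-sided by permutation, exactly where there were at most 100000 splits and otherwise with 100000 resamples, given at least 2 modified and 5 reference clones. The 382 tests of targets and local genes over all groups formed 1 family for Benjamini-Hochberg adjustment, and all captured genes were adjusted within a group. Where clones are few, the splits are too few for a gene alone to pass the adjustment over all captured genes. Local genes are those within 1 Mb of the target. Modifications of the same locus were compared by permutation of each clone's value relative to its own reference. As a check made after the results were seen, Control clones were drawn by whole plate in groups of the size of a modified group, where a date had at least 3 times as many of them, and tested against the other Control clones of the date. Loci were compared with Fisher's exact test. Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1 ran these steps.

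Before the data were examined the rule for named genes was fixed: the target, up to 6 called local genes per group, the 4 called genes outside the window with the largest change, and members of fixed gene lists. The exons of linc1319, counts of single clones, and genes shared between groups of a date were chosen after values were seen. The alternatives fixed beforehand were DESeq2 1.42.0, library size alone, no filter on low counts, a reference of Control clones of any date, a reference of clones of the same date modified on another chromosome, a window of 200 kb, a minimum of 50 allele counts, the allelic fraction, another family for adjustment, and leaving out each clone in groups of 2 to 5.

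Both tests were checked on simulated data, in which clones varied independently, without differences between plates, culture series or dates. Among real Control clones of 150126 the plate as a factor called 91.9% of genes. The false calls given here therefore do not measure those to be expected among real clones. Counts drawn for the linc1405 promoter deletion (10 clones against 63, 573 genes, 200 changed) gave back 70.2% of genes changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 100% of those changed by 2, with 2 false calls in 180. For the linc1319 5ss deletion (2 clones against 15, 510 genes) the shares were 32.8%, 55.2% and 95.5%, with 5 false calls in 127. Allele shifts of 0.5, 1 and 2 simulated for the linc1536 pAS insertion (7 clones against 9, 369 genes, of which 64, 64 and 66 were shifted) were recovered in 34.4%, 87.5% and 100% of genes, with 5 false calls in 149. So many shifted genes ease the adjustment, and the test finds less where few genes shift. Transcripts below 20 allele counts in a clone gave no ratio.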

Results

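The series measured polyadenylated RNA in clonal lines of an F1 hybrid mouse embryonic stem cell, whose 129 and Castaneus parental chromosomes carry enough sequence differences to assign reads to an allele. Each clone was grown in 2i/LIF, a serum-free medium that holds embryonic stem cells in naive pluripotency, and its library was enriched for chosen transcripts by hybrid selection with probes. The 439 libraries analysed came from 220 unmodified Control clones and from clones modified at 1 of 19 loci as the labels name them, 13 of them long noncoding RNA (lncRNA) loci and 6 of them messenger RNA loci, the latter with 57 clones. Snhg17 and linc1329, named apart in the labels, were read at the same transcript, so the targets are 18 transcripts, 12 of them lncRNAs. The labels divide the modified clones into 37 groups, of which 18 are promoter deletions. The others are insertions labelled pAS, in this study a polyadenylation signal placed to end transcription early, and promoter insertions, splice site, exon and intron changes at linc1319. Allele-assigned counts per library ran from 62149 to 3029484, with a median of 834323. The labels carry 9 date labels, and 6 groups had no Control clone of their date, so their reference was Control clones of other dates. Clones are separate lines, and p-values set differences against the spread between them, taking clones as independent. Plates are not modelled. Among Control clones of 150126 the plate as a factor called 91.9% of genes, so p-values of total counts may be too small.

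Deleting or interrupting the targeted locus lowered its own transcript in most groups. Total counts of the target were lower in 24 of 36 groups tested and higher in 2, and the ratio of the alleles deviated further from the reference in 32 of 35 groups (20 when adjusted over all captured genes of the group). The largest fall among lncRNA promoter deletions was at linc1509 (chromosome 2, 104399302 to 104411322), from 1028 ± 249 CPM (allele-assigned counts scaled to 1e+06 per library; SD, n = 77) to 73.8 ± 122.35 (n = 7), a log2 fold change of -3.89 ± 0.43 (SE). Among messenger RNAs, Slc30a9, a zinc transporter family gene, fell by 2.25 on the log2 scale in 9 clones, and Dicer1, the ribonuclease that matures microRNAs, fell by 1.49 in 4 clones. Crlf3 fell by 1.58 in 9 clones, Rcc1, the nucleotide exchange factor of Ran, by 1.22 in 8 clones, and Gpr19 by 0.99 in 5 clones after promoter deletion and by 0.73 in 14 pAS clones. Snhg3 fell by 1.90 (8 clones), linc1386 by 1.28 (4 clones), linc1423 by 2.24 (9 clones) and linc2025 by 1.86 (8 clones) after promoter deletion. Totals of some targets were also lower where another locus was deleted: among promoter deletion groups of the 150126 date, Gpr19 and linc2025 were called lower outside their windows in 5 each, and linc1423 and linc1329 in 4 each.

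**Figure D1:**
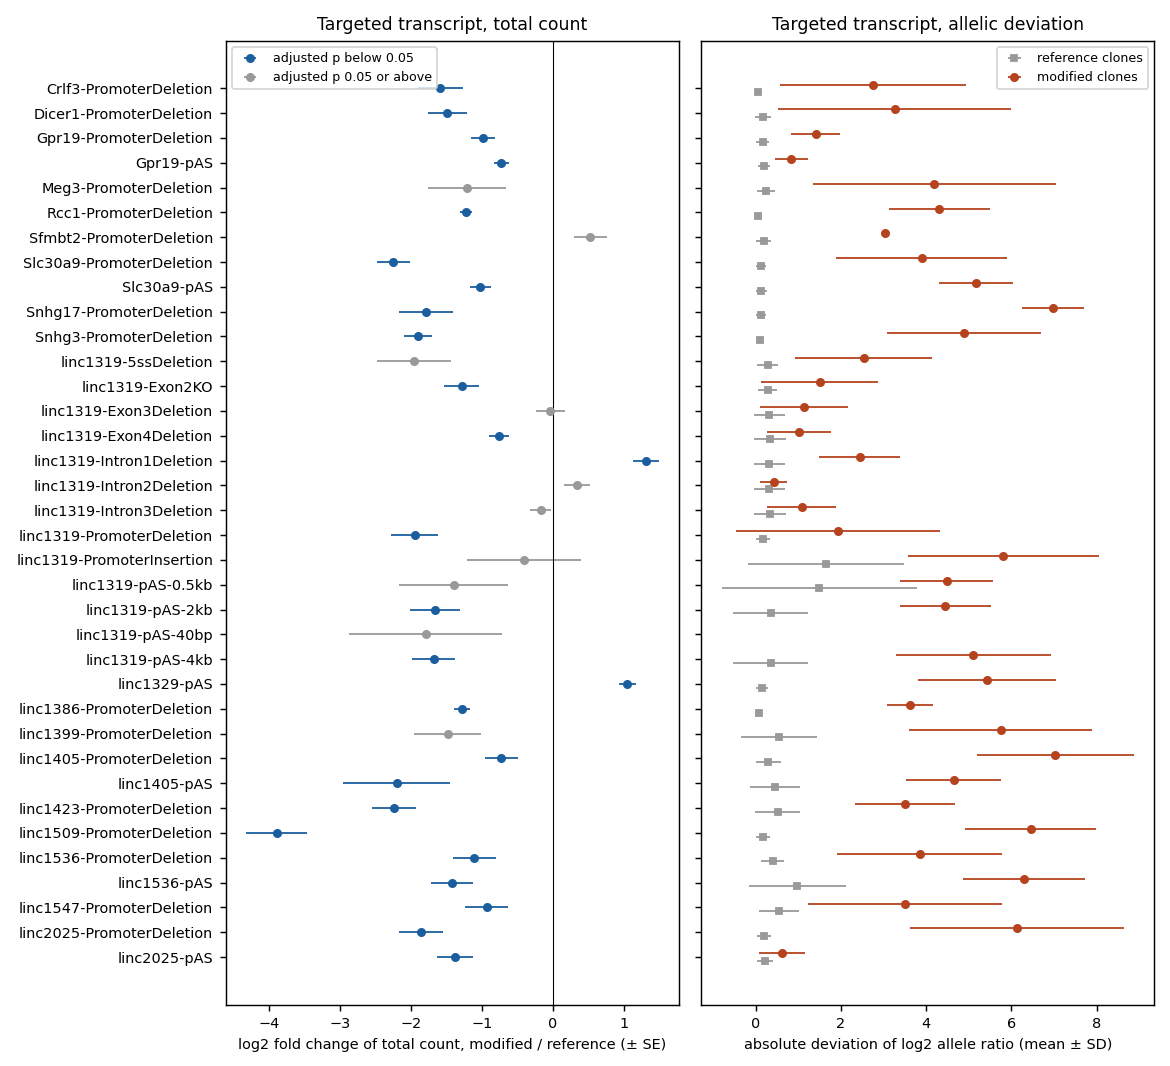
Targeted transcript in each of 36 modification groups. The left panel gives the log2 fold change of the total count with its SE, and the right panel the mean absolute deviation of the log2 allele ratio with its SD in modified and reference clones. Points left of 0 fill most of the left panel, linc1319-Intron1Deletion and linc1329-pAS lie at 1.31 and 1.05, and modified clones deviate further than reference clones in all groups measured.

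Counts per clone showed what lies behind these averages. In the Crlf3 deletion, clone 9 had 4750 counts from the first allele column and 304 from the second, clone 1 had 6032 from the second and a log2 ratio of -4.88, and clone 8 had 13 and 12. At linc1405 (chromosome 9, 118306222 to 118315297), clone 1 had 857 counts from the first column and 0 from the second, and clone 8 had 2 and 80. The total of linc1405 therefore ran from 3.56 to 851 CPM over 10 clones, and its log2 fold change of -0.73 ± 0.24 (adjusted p 0.0139) coexisted with an absolute allelic deviation of 7.03 ± 1.84 (SD, n = 9) against 0.30 ± 0.29 in 63 reference clones. Against 19 clones of the same date modified on other chromosomes, the fold change of linc1405 was -0.74 with an adjusted p of 0.344 in edgeR. That reference holds fewer clones, and the lost call does not show a smaller difference. The labels do not say which allele of a clone was modified, nor which column is 129 and which is Castaneus, so the ratios here are of the first column over the second.

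In 10 groups the target's total did not pass the test. Meg3 averaged 1482 ± 1797 CPM in 6 deletion clones and 3468 ± 817 in 15 reference clones (log2 fold change -1.21, adjusted p 0.181, and 0.22 against Control clones of any date), while its absolute allelic deviation was 4.19 ± 2.86 against 0.24 ± 0.21 (permutation test, adjusted p 0.000454). In the libraries labelled Sfmbt2-PromoterDeletion, Sfmbt2 was at 1803 ± 564 CPM (n = 2) against 1222 ± 345 in 63 reference clones, a log2 fold change of 0.53 ± 0.23, although its allelic deviation of 3.04 exceeded 0.18 ± 0.17 in the reference. The same was so of linc1399, at 21.2 ± 22.7 CPM in 7 clones and 61.4 ± 17.9 in 15, with allelic deviations of 5.75 and 0.53. The remaining 7 groups were all at linc1319: the 5ss deletion, the exon 3, intron 2 and intron 3 deletions, the promoter insertion and the pAS insertions at 40 bp and 0.5 kb.

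The question of the series was whether genes within 1 Mb of a modified locus change on the modified chromosome itself. Sfmbt2, Eomes, Cdkn1b, Snhg11, Rcc1 and the imprinted RNAs Rian, Mirg and Rtl1 passed the allelic test when a neighbour was modified. Bend4 passed too, but in groups where 7.11% and 12.4% of allelic tests outside the window passed. Not all of these calls held under each alternative: that of Eomes ended against Control clones of any date (permutation test, adjusted p 0.0668). Of 347 tests of a local gene, 37 passed the allelic permutation test (21 when adjusted over all captured genes of the group), in 21 of 36 groups, and 36 of these had the larger deviation in modified clones, Emp1 in Gpr19-pAS being the exception, a call that ended with only the clones that share a date with Control clones (adjusted p 0.164) or with clones modified elsewhere as the reference (-0.08, adjusted p 0.804). With the wider adjustment the calls of Emp1, Tcl1, Vill, Chd2 and those of Sfmbt2 in 4 groups were among those that ended. In groups of few clones a gene alone cannot pass it, as in Dicer1-PromoterDeletion with 3876 splits for 465 genes. Of the 37, 23 lay within 200 kb. By total count, 31.4% of 370 local tests passed, 49 higher and 67 lower. Both tests passed in 21 pairs of a group and a local gene, 7 higher and 14 lower, with Sfmbt2 and Snhg11 in more than 1 group. These pairs are not all separate neighbours. 1810026B05Rik overlaps its target linc2025, and 2010009K17Rik and Rprd1b overlap each other, with near-equal values in linc1329-pAS. Where both ratios were measured, the neighbour deviated to the same side as the target in 62.3% of clones, a count made after the data were seen. Outside the window 19.3% of total count tests passed, so a difference in total alone was frequent anywhere in the capture. These shares pool groups of different rates, and the inside share was the higher in 21 of 36 groups. Within single groups, Fisher's exact test of inside against outside gave an unadjusted p below 0.05 only in linc1319-Intron1Deletion (p = 0.0256, 1 of 5 local genes called).

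Under several modifications of linc1319 (chromosome 2, 10249878 to 10286859) a local change was called at Sfmbt2, a Polycomb group gene that starts 5.218 kb away. In 5 clones with the linc1319 promoter deleted, Sfmbt2 was at 562 ± 584 CPM against 1222 ± 345 in 63 reference clones, a log2 fold change of -1.19 ± 0.25 (adjusted p 0.00317). Its absolute allelic deviation was 1.68 ± 1.46 against 0.18 ± 0.17 (permutation test, adjusted p 0.000395), to the same side as that of linc1319 in 5 of 5 clones (exact sign test, p = 0.0625, the smallest that 5 clones allow). In clones with insertions labelled pAS the log2 fold change of Sfmbt2 was -1.25 ± 0.29 at 2 kb (5 clones) and -1.04 ± 0.24 at 4 kb (7 clones), with allelic deviations of 0.95 ± 0.31 and 0.98 ± 0.55 against 0.25 ± 0.22 and 0.25 ± 0.21. These 2 groups had reference clones of other dates and 46.6% and 56.4% of genes outside the window called, so their totals cannot be credited to the insertion. Of allelic tests outside the window 6.05% and 12.2% passed in them as well, so the allelic deviation of Sfmbt2 was not singled out either. At 0.5 kb the allelic deviation of Sfmbt2 was 1.81 ± 0.83 against 0.36 ± 0.30 (4 clones), and at 40 bp it was 2.37 ± 1.17 (3 clones), while neither total passed the test. Adjusted over the local genes alone, the total of Sfmbt2 at 40 bp did pass (log2 fold change -2.29, adjusted p 0.0392 in edgeR). The promoter insertion gave an allelic deviation of 1.31 ± 0.99 (9 clones). Adjusted over all captured genes of the group, these 3 allelic calls ended (adjusted p 0.489, 0.955 and 0.638). At 0.5 kb and 40 bp there were 1820 and 455 splits for 413 and 441 genes tested. A gene alone could not pass there whatever its deviation, so the loss in those groups decides nothing. The total call in the promoter deletion ended without clone 3 (log2 fold change -0.92, adjusted p 0.154), against Control clones of any date (-1.09, adjusted p 0.130) and against clones of the date modified elsewhere (-0.92, adjusted p 0.5684), whereas the allelic call held in all 12 alternatives run.

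**Figure D2:**
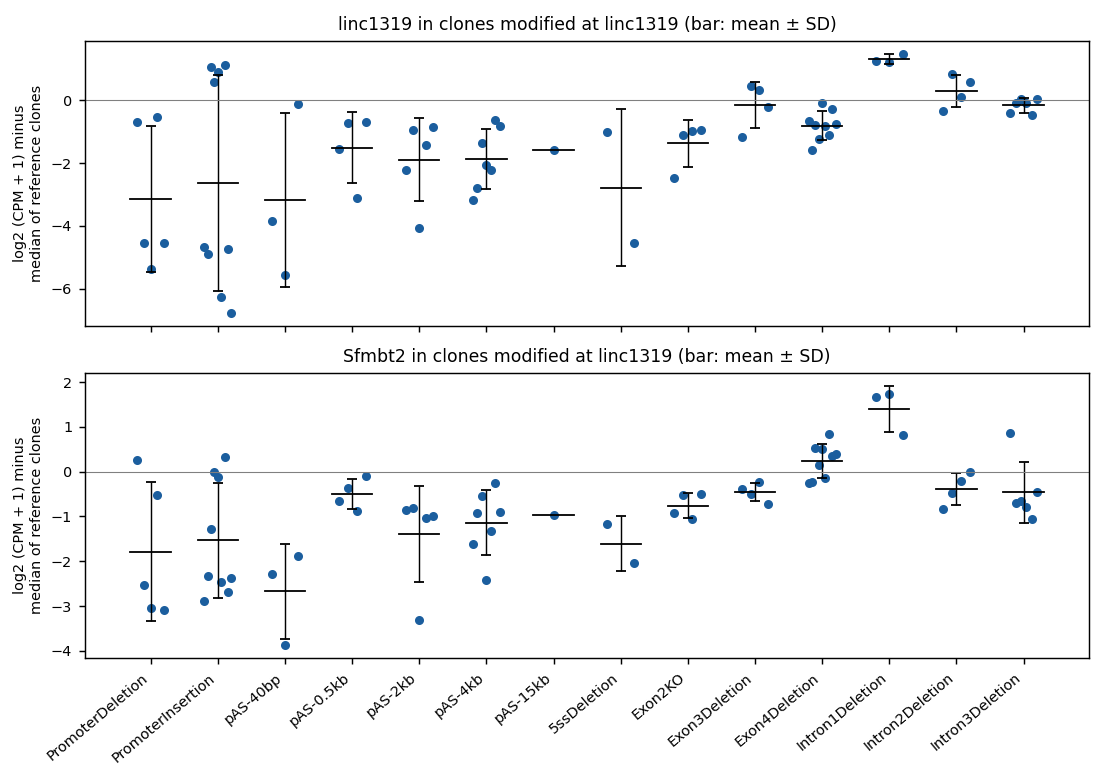
Total counts of linc1319 and Sfmbt2 in each clone modified at linc1319, as log2 of CPM plus 1 minus the median of the reference clones, by modification. Points are clones, bars are means with SD, and the line at 0 is the reference median. Both transcripts lie below 0 in clones of the pAS 2 kb and 4 kb insertions and above it in the 3 clones with intron 1 deleted.

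Changes inside linc1319 split. Deleting intron 1 raised linc1319 by 1.31 ± 0.18 and Sfmbt2 by 1.40 ± 0.20 on the log2 scale (adjusted p 7.55e-06 and 2.19e-05, 3 clones against 29), and the allelic deviation of Sfmbt2 was 4.19 ± 0.91 against 0.32 ± 0.42. Both ratios moved to the same side in 3 of 3 clones. Against Control clones of any date the total of Sfmbt2 gave 1.12 with an adjusted p of 0.0601, and its allelic call ended when adjusted over all captured genes of the group (adjusted p 0.0894). The permutation p behind that value, 0.000202, is the smallest that 4960 splits allow. Sfmbt2 did not pass the test in the exon 3, exon 4, intron 2 or intron 3 deletions, where its log2 fold changes were -0.51, 0.23, -0.42 and -0.36, nor in the exon 2 knockout or the 5ss deletion, where they were -0.86 ± 0.28 (4 clones) and -1.71 ± 0.43 (2 clones; adjusted p 0.362). Adjusted over the local genes alone, Sfmbt2 did pass in the exon 2 knockout and the 5ss deletion (edgeR, unadjusted p 0.00532 and 0.000726). No local gene did so in the exon 3, exon 4, intron 2 or intron 3 deletions. The exon 2 knockout and the 5ss deletion therefore do not show Sfmbt2 to be unchanged. With DESeq2, 1 local gene was called in the 5ss deletion and linc1319 itself passed.

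Exon counts, listed separately in libraries of the 150801 and 151101 dates, were lower on average for the exons deleted. Exon 4 of linc1319 was at 39.96 ± 33.4 CPM in 9 exon 4 deletion clones against 177.8 ± 53.4 in 29 reference clones, and exon 2 was at 25.5 ± 37.7 in 4 exon 2 knockout clones against 202.35 ± 51.6 in 15. With exon 3 deleted, exon 3 was at 207.6 ± 189.3 (from 21.7 to 470 over 4 clones) against 433 ± 110 and exon 4 at 297 ± 167.85 against 177.8 ± 53.4. With intron 1 deleted, exon 3 was at 1138 ± 104.85 and exon 4 at 605 ± 65.3, while exon 2 stayed at 160.9 ± 10.6 against 187.35 ± 49.4. In the 2 clones of the 5ss deletion, exon 2 was at 0 and 110.7 CPM. These exon values are given without a test.

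Eomes, a T-box factor of mesendoderm, lies 72.01 kb from linc1405 and was lower in all 10 deletion clones: a median of 181.5 CPM against 234.4 in 63 reference clones, a log2 fold change of -0.42 ± 0.12 (adjusted p 0.00792). Its absolute allelic deviation was 0.83 ± 0.56 against 0.19 ± 0.15 (permutation test, adjusted p 0.000174), and it deviated to the side of linc1405 in 8 of 9 clones (exact sign test, p = 0.0391). Against 19 clones of that date modified on other chromosomes, the total of Eomes gave -0.54 with an adjusted p of 0.123 in edgeR. The call was thus lost with fewer reference clones and no smaller estimate. Against Control clones of any date the allelic deviation of Eomes had an adjusted p of 0.0668 (permutation test). Vill, 647 kb away, deviated to the other side in 8 of the 9 clones, that is to the same side in 1 (exact sign test, p = 0.0391), and its allelic call ended against clones of that date modified elsewhere (0.22, adjusted p 0.294). In the 2 linc1405-pAS clones Eomes did not pass either test.

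With the Meg3 promoter deleted, allele ratios of other RNAs of the imprinted Dlk1-Dio3 cluster deviated. The absolute allelic deviation of Rian was 2.86 ± 1.97 against 0.23 ± 0.13, that of Mirg 4.63 ± 2.76 against 0.30 ± 0.23, and that of Rtl1, a retrotransposon-derived gene read on the opposite strand from its antisense RNA, 4.69 ± 1.31 against 0.38 ± 0.30. Rian moved to the same side as Meg3 in 6 of 6 clones (exact sign test, p = 0.0312). None of the 3 passed by total count: Rian was at 3343 ± 4238 CPM against 8466 ± 1933, so clones differed widely. The counting is not stated to use strand, so reads of Rtl1 and its antisense RNA cannot be told apart.

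Genes near the promoters of messenger RNA genes also differed. Without the Gpr19 promoter, Cdkn1b, the cyclin-dependent kinase inhibitor 22.5 kb away, fell by 1.07 on the log2 scale (1684 ± 502 CPM in 5 clones against 3613 ± 1387 in 77; adjusted p 0.0209). Its allelic deviation was 0.74 ± 0.43 against 0.11 ± 0.12 and took the side of Gpr19 in 5 of 5 clones (exact sign test, p = 0.0625). The total call of Cdkn1b ended in 4 of the 5 fits that left out a clone, with adjusted p-values from 0.0516 to 0.0572, while the allelic call held. The log2 fold changes in those 4 fits, from -0.92 to -1.11, were about as large as with all clones. The total of Cdkn1b was also lower in 3 and higher in 4 promoter deletion groups of that date where it is not a neighbour. In the Dicer1 deletion, Tcl1, an Akt coactivator abundant in embryonic stem cells, fell by 0.71 (adjusted p 0.00421), with an allelic deviation of 0.58 ± 0.32 against 0.12 ± 0.12. The total call of Tcl1 ended without clone 1 (log2 fold change -0.62 in place of -0.71, adjusted p 0.0515), and its allelic call ended once the ratio was taken relative to the rest of the chromosome (adjusted p 0.110) and against Control clones of any date (adjusted p 0.174).

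Rcc1 and Snhg3, 6.182 kb apart on chromosome 4, could be compared in both directions. Rcc1 in Snhg3 deletion clones had an allelic deviation of 0.38 ± 0.11 against 0.05 ± 0.04, to the side of Snhg3 in 7 of 8 clones (exact sign test, p = 0.0703), with a total log2 fold change of -0.15 ± 0.07 that did not pass. In Rcc1 deletion clones, Snhg3 fell by 0.39 and Trnau1ap, a gene 2.38 kb away, rose by 0.62 ± 0.11 (adjusted p 7.53e-06). In this group 46.7% of genes outside the window were called by total count and 44.4% inside, so these totals were not singled out. Of 36 local genes tested there by allele ratio, Trnau1ap alone passed, and Snhg3 did not. The ratio of Trnau1ap moved away from the side of Rcc1 in all 8 clones (0 of 8 on its side; exact sign test, p = 0.00781), with a deviation of 0.23 ± 0.10 against 0.08 ± 0.08, a call that ended against clones of the date modified elsewhere (adjusted p 0.270). Bend4 deviated by 0.52 ± 0.30 against 0.18 ± 0.20 in Slc30a9 deletion clones and by 0.88 ± 0.51 in linc1536 deletion clones, with totals that did not pass. In these 2 groups 7.11% and 12.4% of allelic tests outside the window passed as well, so Bend4 was not singled out there. No local gene passed the allelic test in the Crlf3 deletion, where Suz12, a core Polycomb subunit 12.4 kb away, had a total log2 fold change of -1.004 ± 0.32, against -1.69 ± 0.37 in the linc2025 deletion, where it is on another chromosome.

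At the other lncRNA loci, Snhg11 changed by both tests. The Snhg17 deletion was read at the transcript listed as linc1329, which lies between Lbp and Snhg11 where the reference table has Snhg17. In those 5 clones Snhg11 fell by 1.42 on the log2 scale (182.2 ± 135.7 CPM against 491 ± 238; adjusted p 0.00259), with an allelic deviation of 1.43 ± 1.05 against 0.26 ± 0.19. In linc2025 deletion clones Chd2, a chromatin remodeller 2.288 kb away, rose by 0.35 ± 0.12 and its ratio moved away from the side of linc2025 in 5 of 5 clones (0 on its side; exact sign test, p = 0.0625), while 1810026B05Rik, which overlaps linc2025, fell by 1.89. Tnni1, 885 kb from linc1423, fell by 1.42, Evx1, 193.8 kb from linc1547, fell by 0.82, and Lmo2, 577 kb from linc1509, fell by 1.79, the last 2 by total count alone. Against clones of the date modified elsewhere, Evx1 gave -0.33 (adjusted p 0.993) and the allelic call of Tnni1 ended (adjusted p 0.310). Tnni1 fell as much in the linc1509 deletion (-1.45), where it is not a neighbour. No local gene passed the allelic test at linc1386, where 2 local genes were testable by total count, or at linc1399, linc1509 and linc1547.

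In linc1329-pAS clones linc1329 was higher, at 4083 ± 1878 CPM (n = 5) against 1767 ± 257 in 86 Control clones of other dates, and Snhg11 was at 3350 ± 653 against 639 ± 503. The log2 fold changes were 1.05 ± 0.12 and 2.29 ± 0.30. Against 17 clones of the same date modified on other chromosomes, linc1329 stayed higher at 1.69 ± 0.16, and Snhg11 was at -0.04 ± 0.21 (adjusted p 0.896). The allelic deviation of Snhg11, 0.89 ± 0.56 against 0.25 ± 0.19, still passed against those clones (permutation test, adjusted p 0.00730). Snhg11 took the side of linc1329 in 3 of 5 clones, so its deviation did not follow that of linc1329. Its ratios ran from 0.58 to 2.12 around a reference median of 0.68, and those of linc1329 from -5.35 to 7.26. With the same exchange of reference, Bend4, linc1536 and Atp8a1 in Slc30a9-pAS clones went from 0.87, 0.92 and 0.52 to -0.09, -0.17 and -0.09, and Rgma in linc2025-pAS clones went from -2.01 to 0.81. The total counts of these local genes therefore depended on which clones were the reference. The references exchanged differ in date, in being modified elsewhere and in number (86 Control clones against 16, 17 and 18), which cannot be told apart here.

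Promoter deletions at lncRNA and messenger RNA loci were compared by whether any local gene was called. At least 1 local gene passed the total count or allelic test at 10 of 12 lncRNA loci and at 6 of 6 messenger RNA loci, a difference of -16.7 percentage points (Fisher's exact test, two-sided, p = 0.529). By the allelic test alone the numbers were 8 of 12, with Sfmbt2, Eomes, Rian and Snhg11 among the genes, and 4 of 6, with Cdkn1b, Tcl1, Trnau1ap and Bend4. Within 200 kb they were 9 of 12 and 4 of 6, a difference of 8.33 points (p = 1). With 18 loci only a large difference could have passed. Outside the windows 13.9% of total count tests passed in groups with controls of their date, so a call is likely wherever many local genes are tested. The loci without one, linc1386 and linc1399, had 2 and 3 local genes tested by total count, against 36 at Rcc1. Some loci of both classes, such as Rcc1 and Snhg3, also share local genes. This comparison therefore cannot tell the classes apart.

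Modifications of the same locus were compared in 18 pairs of groups, none sharing a date, each clone set against its own reference. Over the target and called local genes of each pair, 16 permutation tests passed (9.697%) at an adjusted p below 0.05. Sfmbt2 was lower in the linc1319 promoter deletion than in the exon 4 deletion by 2.02 on the log2 scale (adjusted p 0.0449), and linc1319 was lower than in the intron 3 deletion by 2.98 (adjusted p 0.0325). Cdkn1b was lower in the Gpr19 promoter deletion than in the pAS clones by 1.37, and its allelic deviation was larger by 0.49. Bend4 deviated more in the linc1536 promoter deletion than in the pAS clones by 0.78. The rest were totals of Emp1, Hebp1, Atp8a1, Bend4, Uchl1, linc1536, Taf3, Rgma, Slco3a1 and St8sia2. Leaving out clones gave 6 to 12 such calls and Control clones of any date 29. With clones of the date modified elsewhere as the reference, where a group had them, 10 of the 16 were called again, linc1536 at Slc30a9 with a difference of -0.40 in place of -1.63 and Uchl1 at linc1536 with -1.53 in place of -0.56, and those of Atp8a1, Sfmbt2 (-1.76, adjusted p 0.0753), Rgma (which turned to -0.64), Slco3a1, St8sia2 and the total of Bend4 ended.

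Away from the modified loci many captured genes differed in total count. Slc16a3, a monocarboxylate transporter, was at 1825 ± 1273 CPM in 77 Control clones of the 150126 date and at 271 ± 91.4 in Gpr19, 315 ± 104.6 in Slc30a9, 298 ± 108.9 in Snhg17, 455 ± 124.4 in Snhg3 and 259 ± 80.5 in linc1536 deletion clones of that date. Tgm2, a transglutaminase, was at 149.6 ± 113.2 CPM in the same controls and at 511 ± 160, 661 ± 244, 550 ± 136.65 and 584 ± 160.6 in the Crlf3, Rcc1, linc1423 and linc2025 deletions, and lower, at 52.3 ± 18.9, in the Slc30a9 deletion. Unmodified plates of that date differed in these genes too: against the other Control clones, Slc16a3 ran from -2.89 to 1.17 on the log2 scale over 25 plates and was lower by 1 or more in 7, and Tgm2 ran from -2.17 to 1.20. Control clones drawn by whole plate, in groups of the size of the modified ones, called up to 53.6% of genes. Ly6f and St8sia2 were lower in groups of the second set, and Slc32a1 and Mb in groups of the first. Over 36 groups the genes called ran from 0 to 320, and the median share was 11.6% of genes tested. The share outside the window was 13.9% in the 30 groups with controls of their date and 46.4% in the 6 without. Against clones of their date modified on other chromosomes, the share of genes called by edgeR went from 30.5% to 0 in the linc1405, from 29.3% to 0 in the linc1547 and from 6.59% to 0 in the linc1319 deletion, while with the same exchange it rose, among others, from 28.1% to 41.6% in the Slc30a9, from 12.66% to 28.99% in the linc1509 and from 6.66% to 10.2% in the linc1386 deletion. In the linc1405, linc1547 and linc1319 deletions the exchanged reference held 19, 21 and 22 clones in place of 63, so fewer clones may also have cost calls. In the linc1386 deletion it held 25 in place of 63. Allele ratios changed less widely: outside the window 0.759% of tests passed in the 30 groups and 10.96% in the 6, and most of those in the 30 groups were in the Slc30a9 (30) and linc1536 (46) deletions.

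**Figure D3:**
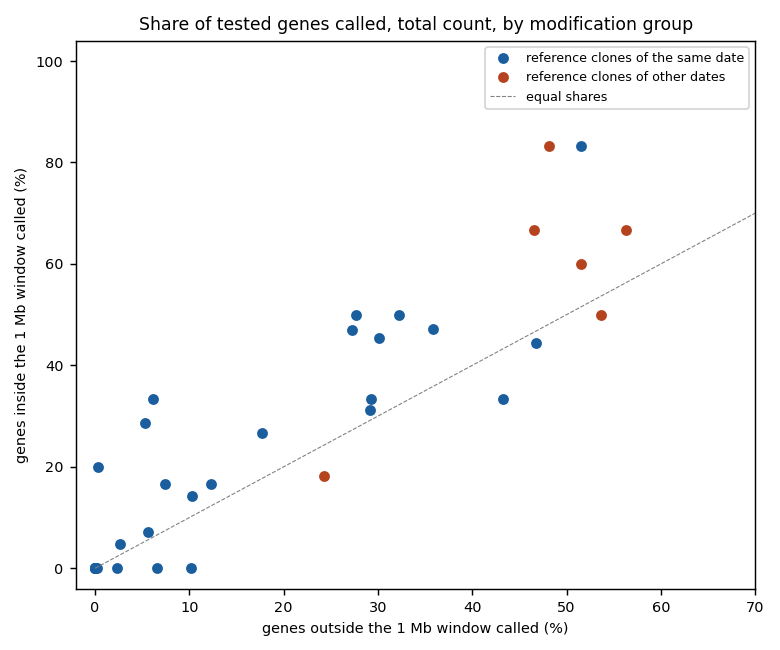
Share of tested genes called by total count outside the 1 Mb window (horizontal axis, percent) and inside it (vertical axis, percent), 1 point per modification group. The 6 groups whose reference clones were of other dates are drawn in a second colour, and the dashed line marks equal shares. Over all groups 19.3% of outside tests and 31.4% of inside tests passed. These pooled shares mix groups of different rates and numbers of local genes. The inside share was the higher in 21 of 36 groups.

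Among the 10 promoter deletion groups of the 150126 date, which share their 77 Control clones, 37 genes outside the windows were higher and 75 lower in at least 4 groups. Groups of those Control clones drawn singly gave 0 such genes by edgeR in each of 9 draws, and groups drawn by whole plate gave at most 10 higher and 13 lower in 100 draws. Neither covers groups grown in the same culture series, which could share genes without an effect of the modification. Independent lists of the observed sizes would give 15.8 and 37.5. With the Control clones divided between alternate groups the numbers were 32 and 62. Cdx4 and Snhg12 were lower in 6 of the 10 groups and Slc16a3 in 5.

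Gene lists fixed beforehand had members in the capture of 21 groups. Of the pluripotency list, Nanog and Dppa3 gave 4 calls in 42 tests (11 when adjusted over the list alone): Nanog was higher in linc1319-pAS-2kb and linc1319-pAS-4kb clones, at 39298 ± 4971 and 37229 ± 2567 CPM against 23745 ± 4906, and lower in the intron 2 deletion, and Dppa3 was lower in the 4 kb insertion. Eomes and Nes, of the list of primed and early differentiation genes, gave 7 calls in 42 (15 when adjusted over the list alone), with Nes at 585 ± 136.3 and 589 ± 122.4 CPM against 1557 ± 482 in the same pAS groups. The 8 imprinted genes of the Dlk1-Dio3 cluster gave 13 calls, 8.609% of tests (22 when adjusted over the list alone), 4 higher and 9 lower, among them Mirg lower in the linc1405 and linc1547 deletions, calls that ended against clones of the date modified elsewhere (0.02 and -0.15), and Dio3 lower in both pAS groups. Gapdh and Hprt gave 4 in 42 (5 when adjusted over the list alone). The shares were 9.52% for the pluripotency list, 16.7% for primed and early differentiation genes and 9.52% for Gapdh and Hprt. Over all 36 groups the median share of genes called was 11.6%, and the lists were not tested against it. Of all genes tested, 46.9% were called in linc1319-pAS-2kb and 56.5% in linc1319-pAS-4kb, so Nanog, Nes and Dio3 were not singled out there. In the 2 kb and 4 kb pAS groups, whose reference clones were of other dates, Hoxa9 was at 0.720 and 0 CPM against 89.5 ± 91.5 and Hoxa11 at 0 and 0.329 against 51.5 ± 48.99. Markers of extraembryonic, fibroblast and two-cell-like cells had 0 members in the capture.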

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

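The splits of clones between groups, the draws of whole plates, the exchange of reference for modifications of the same locus, the relation of library size within dates, the counting of allelic calls left as calls shared with the first test, and the test of linc1329 alone against clones of its own date were chosen only after the results were seen.

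Many captured genes outside the 1 Mb windows differed in total count between modified and reference clones. Plates of Control clones argued against neither side: 8.451% of single plates called 10% or more of the genes against the other Control clones of their date, between the bounds of 5% and 25% set before. The plate as a factor called 91.9% of genes among Control clones of 150126 and 80.2% in 141107, and since the plates of modified clones are not in the labels, a difference between culture series cannot be told apart from the modification. Another date of the reference could account for part: against clones of the same date modified elsewhere, 2 of 4 groups fell under the 6.983% median of groups with Control clones of their date (Slc30a9-pAS from 53.66% to 0%, linc2025-pAS from 48.16% to 1.786%, linc1329-pAS from 51.55% to 10.32%, linc1405-pAS from 24.23% to 12.52%). Those references held 13 to 18 clones in place of 86 or 90, which may by itself lower the share. The share rose with the difference in library size over 36 groups (Spearman 0.4275, permutation p = 0.00997), so library size may account for part, although among the 30 groups with Control clones of their date the relation did not pass (0.1511, p = 0.425) and date goes together with library size.

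Allele ratios deviated at 404 tests outside the windows, adjusted over all captured genes of a group, and at 37 inside, adjusted over targets and local genes (21 with the adjustment used outside). Outside, 44.55% of the calls were also made with counts thinned to those of the modified clones, so depth may account for many. Of the calls, 65.35% were also made relative to the rest of the chromosome, which argues against chromosome gain or loss as the whole cause. On the X chromosome were 39, so X-linked genes alone did not make up the calls. Whether 1 X allele goes with deviations at autosomal genes was not tested, so that cause stays open. All clones of Slc30a9-pAS, linc1329-pAS and linc2025-pAS had X-linked counts near 1 allele, with 38, 64 and 68 autosomal calls. Of the Control clones of 150126, most of their reference, 0 of 76 did. In linc1319-pAS-2kb and linc1319-pAS-4kb, where 1 clone did, 31 and 63 autosomal calls were made. Inside, 70.27% were also made after thinning and 83.78% relative to the rest of the chromosome, which argues against depth and chromosome gain or loss as the whole cause. An effect of the modified locus on its own chromosome is the biological explanation for the calls inside, as a hypothesis, found and tested in the same data.

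In linc1329-pAS clones linc1329 and Snhg11 were higher than in Control clones of other dates. Against clones of the same date modified elsewhere the log2 fold change of Snhg11 was -0.04139, so the date of the reference may account for the total of Snhg11, whose allelic deviation still passed there (0.828 more than the reference, permutation test, adjusted p 0.007302), while that of linc1329 was 1.688 (SE 0.1602), which argues against it for linc1329. No single clone accounted for the rise, the estimate closest to 0 being 0.8086 without clone 3. An effect of the insertion on linc1329 remains a hypothesis. Snhg11 deviated to the side of linc1329 in 3 of 5 clones, so its allelic call does not show a change on the modified chromosome.

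Single clones stood far from the others of their group in 8 of 53 groups of values, where chance gives about 1 in 20. Relative to the reference on the log2 scale, the target was at -1.679 in clone 4 of the Rcc1 deletion, -7.247 in clone 7 of the Snhg3 deletion, -2.472 in clone 1 of linc1319-Exon2KO and -7.169 in clone 7 of the linc1405 deletion. The absolute allelic deviation of the target was 0.03361 in clone 6 of the Slc30a9 deletion, 0.896 in clone 7 of the Snhg3 deletion, 2.586 in clone 5 of linc1329-pAS and 2.377 in clone 4 of the linc1405 deletion.

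Modifications of the same locus differed by permutation test in 16 values, here as the promoter deletion minus the other modification and all between dates. At Gpr19, against pAS, Cdkn1b differed by -1.37 in log2 total and 0.4903 in allelic deviation, Emp1 by -2.388 and Hebp1 by -1.65. At Slc30a9, against pAS, Atp8a1 differed by -0.6587, Bend4 by -1.49, Uchl1 by -1.163 and linc1536 by -1.631. At linc1319, Sfmbt2 differed by -2.024 from the exon 4 deletion, linc1319 by -2.979 from the intron 3 deletion and Taf3 by 0.2003 from the 4 kb pAS insertion. At linc1536, against pAS, Bend4 differed by 0.7829 in allelic deviation and Uchl1 by -0.5625. At linc2025, against pAS, Rgma differed by 1.851, Slco3a1 by -1.992 and St8sia2 by 3.175. With clones of the date modified elsewhere as the reference the totals of Atp8a1 (-0.1603), Bend4 (-0.3488), Rgma (-0.6442), Slco3a1 (-0.4174), St8sia2 (0.9962) and Sfmbt2 (-1.761) no longer passed, so the date of the reference may account for those at Slc30a9 and linc2025. The difference of linc1536 at Slc30a9 still passed but fell to -0.3967.

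Each count of genes called was set beside 100 splits of the same clones, the real split included, in groups of at least 3 clones. Fewer than 1 in 20 of the splits gave as large a count for 27 of 33 counts over all genes and for 23 of 23 counts of local genes, with the real split the only split as large in 24 and 21 of them. This argues against chance in which single clones fell into a group, without an adjustment over these counts. Local counts were given only for groups with at least 1 local gene called, so few equal splits were likely from the start. In linc1319-Exon4Deletion the 1 gene counted was the target itself. As large a count came from 2 splits for Meg3-PromoterDeletion, from 4 for linc1319-Exon4Deletion and from 4 for linc1319-Intron1Deletion, and for local genes from 3 for Meg3-PromoterDeletion and 3 for linc1319-Intron1Deletion. Chance was left open for linc1319-Exon2KO (7 splits), linc1319-PromoterInsertion (8 splits), and linc1319-Exon3Deletion, linc1319-Intron3Deletion, linc1319-pAS-0.5kb and linc1319-pAS-40bp (100 splits each, the real count being 0). The share of genes called in the real split and in the highest other split follows for each group. Crlf3-PromoterDeletion 43.07% against 2.521%, Dicer1-PromoterDeletion 2.924% against 0.5848%, Gpr19-PromoterDeletion 18.12% against 6.823% and Gpr19-pAS 10.61% against 1.806%. Meg3-PromoterDeletion 5.653% against 10.33%, Rcc1-PromoterDeletion 46.65% against 1.255%, Slc30a9-PromoterDeletion 28.09% against 24.89% and Slc30a9-pAS 53.72% against 10.19%. Snhg17-PromoterDeletion 29.51% against 17.41%, Snhg3-PromoterDeletion 36.86% against 11.65%, linc1319-Exon2KO 0.1969% against 12.2% and linc1319-Exon3Deletion 0% against 1.893%. linc1319-Exon4Deletion 0.1701% against 0.1701%, linc1319-Intron1Deletion 0.6873% against 4.983%, linc1319-Intron2Deletion 10.07% against 0.6826% and linc1319-Intron3Deletion 0% against 1.365%. linc1319-PromoterDeletion 6.586% against 6.239%, linc1319-PromoterInsertion 0.198% against 2.97%, linc1319-pAS-0.5kb 0% against 7.071% and linc1319-pAS-2kb 46.9% against 0.177%. linc1319-pAS-40bp 0% against 6.903%, linc1319-pAS-4kb 56.54% against 28.98%, linc1329-pAS 51.92% against 30.13% and linc1386-PromoterDeletion 6.655% against 6.305%. linc1399-PromoterDeletion 2.321% against 0.3868%, linc1405-PromoterDeletion 30.54% against 5.759%, linc1423-PromoterDeletion 28.14% against 10.45% and linc1509-PromoterDeletion 12.66% against 12.45%. linc1536-PromoterDeletion 32.62% against 12.15%, linc1536-pAS 7.801% against 0%, linc1547-PromoterDeletion 29.32% against 14.49% and linc2025-PromoterDeletion 52.01% against 16.49%. linc2025-pAS 48.72% against 1.915%. For local genes the counts were as follows. Crlf3-PromoterDeletion 5 against 1, Dicer1-PromoterDeletion 1 against 0, Gpr19-PromoterDeletion 4 against 2, Gpr19-pAS 2 against 1 and Meg3-PromoterDeletion 1 against 2. Rcc1-PromoterDeletion 16 against 1, Slc30a9-PromoterDeletion 3 against 2, Slc30a9-pAS 3 against 0, Snhg17-PromoterDeletion 5 against 4 and Snhg3-PromoterDeletion 17 against 4. linc1319-Intron1Deletion 1 against 1, linc1319-PromoterDeletion 2 against 0, linc1319-pAS-2kb 4 against 0, linc1319-pAS-4kb 4 against 2 and linc1329-pAS 9 against 2. linc1405-PromoterDeletion 5 against 0, linc1423-PromoterDeletion 8 against 2, linc1509-PromoterDeletion 3 against 1, linc1536-PromoterDeletion 3 against 1 and linc1536-pAS 1 against 0. linc1547-PromoterDeletion 5 against 1, linc2025-PromoterDeletion 5 against 2 and linc2025-pAS 5 against 0. These splits exchange clones between plates and dates, so they do not exclude a difference between batches. In Slc30a9-pAS, linc1329-pAS, linc2025-pAS, linc1319-pAS-2kb and linc1319-pAS-4kb the real split also follows the date, and within the date the first 3 went to the lower shares given above. Of the clones of Gpr19-pAS a part has no Control clones of its date, and with only the others the share was 1.471% and 0 local genes were called by edgeR. Control clones drawn by whole plate within a date gave as large a share in 1 in 20 or more of the draws in 13 of 23 groups, among them the 4 with 0 genes called by edgeR, and none did in 4: Dicer1-PromoterDeletion, Rcc1-PromoterDeletion, linc1405-PromoterDeletion and linc2025-PromoterDeletion. In these 4 the highest draws were 2.14% (of only 20 draws), 45.55%, 25% and 35.17%. In Rcc1-PromoterDeletion that came close to the real 46.65%. The highest share in such draws was 48.73% in Crlf3-PromoterDeletion, 27.54% in Gpr19-PromoterDeletion, 31.78% in Slc30a9-PromoterDeletion, 31.36% in Snhg17-PromoterDeletion, 46.61% in Snhg3-PromoterDeletion, 3.529% in linc1319-Exon2KO, 25.95% in linc1319-Exon4Deletion, 11.94% in linc1319-Intron1Deletion, 22.15% in linc1319-Intron2Deletion, 24.65% in linc1319-PromoterDeletion, 21.68% in linc1386-PromoterDeletion, 53.6% in linc1423-PromoterDeletion, 38.77% in linc1509-PromoterDeletion, 35.81% in linc1536-PromoterDeletion and 30.42% in linc1547-PromoterDeletion, so plates of unmodified clones alone could give shares as large there. Other splits gave high shares in linc1319-pAS-4kb and linc1329-pAS, and more than the real count in several groups, among them Meg3-PromoterDeletion and linc1319-Exon2KO. A structure among the clones apart from the modification could give this, but was not tested.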

How the results depend on the processing

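The ratio relative to the rest of the chromosome, the thinned counts, the groups with Control clones of their date alone and all alternatives for modifications of the same locus were chosen after seeing the data, and the other settings before. The target kept its call and direction under each alternative run in 17 of 26 groups by total count and in 18 of 32 by allele ratio, and 13 of 37 allelic calls of local genes did so. Of 252 fold changes of named genes, 110 did. With clones of the date modified on another chromosome as the reference, 48.53% of the named fold changes refitted lost their call or turned, and with 1 clone left out 37.05% did, a larger number over more fits. The reference of clones modified elsewhere was the smaller in most groups, so a lost call need not mean a smaller difference. No paired analysis was possible because the clones carry no replicate number in the labels. The allelic test recovered 34.4% of simulated shifts of 0.5 with 7 clones against 9, so it can miss shifts of that size. That simulation shifted 64, 64 and 66 of 369 genes by 0.5, 1 and 2, while 1 gene passed over all captured genes in the real group. Over all captured genes the share recovered in real data is therefore likely lower. The cause of the changes below was not tested, except that a window of 200 kb and a left-out clone hold fewer genes or clones. Values are shares of tested genes called in percent, counts of local genes called, log2 fold changes or allelic deviations, in the groups where they moved over 1.5 times, changed call or turned.

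With library size alone in place of TMM factors, local genes called: Crlf3-PromoterDeletion 8 and linc1405-pAS 1. target log2 fold change in linc1319-Exon3Deletion 0.005528. Share of genes called in percent: linc1319-Exon3Deletion 0.1721, linc1319-Exon4Deletion 0.6803, linc1319-Intron1Deletion 1.546, linc1319-Intron3Deletion 1.365 and linc1319-PromoterDeletion 10.75. Without a filter on low counts, local genes called: Crlf3-PromoterDeletion 9 and Gpr19-pAS 1. Share of genes called in percent: linc1386-PromoterDeletion 3.001. Within 200 kb, local genes called: Crlf3-PromoterDeletion 3, Dicer1-PromoterDeletion 0, Gpr19-PromoterDeletion 2, Gpr19-pAS 0, Meg3-PromoterDeletion 0 and Rcc1-PromoterDeletion 6. Sfmbt2-PromoterDeletion 0, Slc30a9-PromoterDeletion 1, Snhg17-PromoterDeletion 2, Snhg3-PromoterDeletion 5, linc1319-PromoterDeletion 1 and linc1319-pAS-2kb 1. linc1319-pAS-4kb 1, linc1329-pAS 2, linc1405-PromoterDeletion 2, linc1405-pAS 0, linc1423-PromoterDeletion 2 and linc1509-PromoterDeletion 0. linc1547-PromoterDeletion 2 and linc2025-pAS 3. Local genes called over all groups 43 and the difference between lncRNA and messenger RNA loci in percentage points 8.333. With DESeq2, share of genes called in percent: Dicer1-PromoterDeletion 7.992, Gpr19-pAS 17.16, Meg3-PromoterDeletion 10.54, linc1319-5ssDeletion 0.3922, linc1319-Exon2KO 2 and linc1319-Exon3Deletion 2.809. linc1319-Exon4Deletion 1.19, linc1319-Intron1Deletion 1.375, linc1319-Intron3Deletion 2.564, linc1319-PromoterInsertion 2.878, linc1319-pAS-0.5kb 1.818 and linc1399-PromoterDeletion 4.15. Local genes called: linc1319-5ssDeletion 1. With Control clones of any date as the reference, share of genes called in percent: Dicer1-PromoterDeletion 20.39, Gpr19-PromoterDeletion 6.223, Gpr19-pAS 65.88, Meg3-PromoterDeletion 38.54, Sfmbt2-PromoterDeletion 0 and Slc30a9-PromoterDeletion 16.95. Snhg17-PromoterDeletion 19.19, linc1319-5ssDeletion 0.1751, linc1319-Exon2KO 20.7, linc1319-Intron1Deletion 0.3497, linc1319-Intron2Deletion 3.497 and linc1319-PromoterDeletion 0.1767. linc1319-PromoterInsertion 63.48, linc1319-pAS-0.5kb 51.24, linc1319-pAS-40bp 30.97, linc1386-PromoterDeletion 0.177, linc1399-PromoterDeletion 45.29 and linc1405-PromoterDeletion 15.52. linc1536-PromoterDeletion 19.96, linc1536-pAS 62.96 and linc1547-PromoterDeletion 12.7. Local genes called: Dicer1-PromoterDeletion 4, Gpr19-PromoterDeletion 2, Gpr19-pAS 12, Meg3-PromoterDeletion 4, Sfmbt2-PromoterDeletion 0 and Snhg3-PromoterDeletion 10. linc1319-Intron1Deletion 0, linc1319-PromoterDeletion 0, linc1319-PromoterInsertion 5, linc1319-pAS-0.5kb 2, linc1319-pAS-40bp 2 and linc1405-PromoterDeletion 3. linc1536-PromoterDeletion 1, linc1536-pAS 3 and linc1547-PromoterDeletion 2. target log2 fold change in Meg3-PromoterDeletion 0.2158, Atp5c1 log2 fold change in linc1319-PromoterDeletion -0.1765, Elf4 log2 fold change in Dicer1-PromoterDeletion -0.3988, Nrbp2 log2 fold change in Gpr19-pAS -0.3354, Bahcc1 log2 fold change in Gpr19-pAS -1.174 and Cct3 log2 fold change in linc1399-PromoterDeletion 0.6329. Gapdh log2 fold change in linc1399-PromoterDeletion 0.8654, Gapdh log2 fold change in linc1405-PromoterDeletion -4.739, the percent of allelic tests called outside the windows 5.459 and calls between modifications of a locus 29. With clones of the date modified on another chromosome as the reference, share of genes called in percent: Dicer1-PromoterDeletion 7.692, Meg3-PromoterDeletion 9.021, Slc30a9-PromoterDeletion 41.63, Slc30a9-pAS 0.2203, linc1319-PromoterDeletion 0 and linc1329-pAS 10.13. linc1386-PromoterDeletion 10.24, linc1399-PromoterDeletion 7.157, linc1405-PromoterDeletion 0, linc1405-pAS 12.43, linc1509-PromoterDeletion 28.99 and linc1536-pAS 4.401. linc1547-PromoterDeletion 0 and linc2025-pAS 1.982. Local genes called: Gpr19-pAS 1, Meg3-PromoterDeletion 2, Slc30a9-PromoterDeletion 5, Slc30a9-pAS 0, linc1319-PromoterDeletion 0 and linc1329-pAS 0. linc1399-PromoterDeletion 1, linc1405-PromoterDeletion 0, linc1405-pAS 0, linc1509-PromoterDeletion 8, linc1536-pAS 0 and linc1547-PromoterDeletion 0. linc2025-pAS 1. Emp1 log2 fold change in Gpr19-pAS -0.3751, Bend4 log2 fold change in Slc30a9-pAS -0.09298, linc1536 log2 fold change in Slc30a9-pAS -0.1651, Atp8a1 log2 fold change in Slc30a9-pAS -0.08885, Atp5c1 log2 fold change in linc1319-PromoterDeletion -0.01093 and Snhg11 log2 fold change in linc1329-pAS -0.04139. D630003M21Rik log2 fold change in linc1329-pAS -0.7047, Dhx35 log2 fold change in linc1329-pAS 0.02913, Rgma log2 fold change in linc2025-pAS 0.8067, 2010009K17Rik allelic deviation in linc1329-pAS -0.008998, Rprd1b allelic deviation in linc1329-pAS -0.01343 and Fam83d allelic deviation in linc1329-pAS -0.05496. Tnni1 log2 fold change in Slc30a9-pAS 0.1337, Rgma log2 fold change in Slc30a9-pAS 0.1284, Crabp2 log2 fold change in linc1386-PromoterDeletion 0.07369, St8sia2 log2 fold change in linc1405-pAS 0.4751, Gapdh log2 fold change in linc1405-PromoterDeletion -0.014 and Hprt log2 fold change in linc1405-PromoterDeletion -0.05255. Mirg log2 fold change in linc1405-PromoterDeletion 0.01951 and the percent of allelic tests called outside the windows 0.8696. With only the Gpr19-pAS clones that share a date with Control clones, share of genes called in percent: Gpr19-pAS 1.471. Local genes called: Gpr19-pAS 0. With the allelic fraction, values were Gata3 allelic deviation in linc1319-pAS-2kb -0.005001. Over the 30 groups with Control clones of their date, values were genes called over all groups 2202 and the percent of allelic tests called outside the windows 0.7586. Adjusted over all captured genes of a group, values were groups with an allelic call of the target 20 and allelic calls of local genes over all groups 21. With counts thinned to the modified clones, values were the percent of allelic tests called outside the windows 1.114. Leaving out 1 clone at a time, share of genes called in percent: Dicer1-PromoterDeletion 0 to 7.407, Gpr19-PromoterDeletion 0.4255 to 4.255, Sfmbt2-PromoterDeletion 0 to 11.52, Snhg17-PromoterDeletion 16.74 to 20.08, linc1319-5ssDeletion 0 to 0.1961 and linc1319-Exon2KO 0 to 0.1961. linc1319-Exon3Deletion 0 to 0.1712, linc1319-Intron1Deletion 0.3436 to 0.6908, linc1319-Intron2Deletion 1.029 to 8.874, linc1319-PromoterDeletion 0.1748 to 13.32, linc1319-pAS-0.5kb 0 to 2.424 and linc1386-PromoterDeletion 0.5245 to 4.211. linc1405-pAS 6.195 to 6.726. Local genes called: Dicer1-PromoterDeletion 0 to 1, Gpr19-PromoterDeletion 0 to 1, Sfmbt2-PromoterDeletion 0 to 3, Snhg17-PromoterDeletion 3 to 4, linc1319-PromoterDeletion 0 to 2 and linc1319-pAS-2kb 2 to 3. linc1329-pAS 4 to 8 and linc1405-pAS 1. target log2 fold change in linc1319-Exon3Deletion -0.2409 to 0.2134, target allelic deviation in linc1319-Intron2Deletion -0.005457 to 0.2211, Picalm log2 fold change in Sfmbt2-PromoterDeletion -1.106 to 2.479, Bzw1 log2 fold change in Sfmbt2-PromoterDeletion -0.7292 to 2.413 and calls between modifications of a locus 6 to 12.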

Other observations

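All values in this part were noticed after the data were examined. X-linked counts lay near 1 allele in all clones of 4 dates: 15 Control and 17 modified clones of 150126-S1 and 12 and 16 of 150216, all to the first allele column, and 9 and 14 of 150416 and 22 modified clones of 1 further date, all to the second. In 150126 this was so of 0 of 76 Control and 0 of 71 modified clones, in 141107 of 4 of 63 and 1 of 29, in 150801 of 0 of 29 and 2 of 26, in 151101 of 4 of 15 and 0 of 6, and in the S1 set of the last of the 4 dates of 1 of 15 modified clones.

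The median ratio of an autosome stood at least 0.5 on the log2 scale from the reference in 8 Control clones (3.636%) and 10 modified clones (4.566%). The shift was -6.26 on chromosome 12 in a Control clone of 141107 and 8.04 on chromosome 16 in clone 1 of the Sfmbt2 promoter deletion. The single linc1319-pAS-15kb clone had linc1319 at 224 CPM and Sfmbt2 at 585 CPM, without a test.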
